A study of Rattus norvegicus with 24 samples.

How the data were processed

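Per the labels' protocols, testis cells were seeded at high density in a matrix gel and kept in serum-free medium, with hormones added to fresh medium. RNA was purified with poly-T beads, copied with random hexamers into non-directional libraries and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, reads were aligned with STAR to the rat build mRatBN7.2, without a stated version, and the counting tool and gene annotation were not given in the sources used here. Values in CPM, each gene's reads scaled to the library total, were deposited by the authors for 21425 genes, of which 19696 matched a reference symbol or synonym. All values were whole multiples of 1 read per library to within 0.01 read, so reads could be recovered, and 2.93 to 3.98% of the baseline reads and 4.25 to 4.71% of the induction reads lay outside the listed genes.

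Each experiment was fitted separately with limma 3.58.1 in R 4.3.3, on log2(CPM + 1), with the group as the only term, an empirical Bayes trend and all 12 libraries. Genes needed at least 1 CPM in at least 3 libraries, which kept 13055 genes in the baseline and 12450 in the induction experiment. Two-sided p-values were adjusted by Benjamini-Hochberg within each of 9 comparisons, and a gene was called at an adjusted p under 0.05. The 37 gene lists, 15 of cell type markers and 22 of programmes, were tested with camera in limma at a preset correlation of 0.01 where at least 3 members were tested, and again with an estimated correlation. Of 476 list symbols 25 were not analysed and 3 were matched by synonym. The tests of the comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except the alternatives named as added later. The tests of explanations, including the splits of the libraries, were chosen after the results were seen.

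Genes were named by a rule. It took the 5 genes that rose and the 5 that fell most among called genes without overlap between the groups and with a mean of at least 5 CPM in the higher group. For a called list it took up to 4 called members in its direction and 1 in the other, and for other lists up to 2 called members. Genes of a fixed panel of hormone response, steroid synthesis and cell types were given where a comparison needed them, whatever their values, and lists could be left out.

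The induction libraries of a litter resembled each other. After group means were removed, 18 pairs of libraries of the same litter had a median correlation across genes of 0.482 (-0.0119 to 0.747), with genes not being independent replicates, and 16 lay above 0.1. The labels also give the litters, so the induction comparisons were repeated with litter as a block. In the baseline experiment the 18 pairs with the same replicate number had a median of -0.000715 (-0.349 to 0.344), 5 of them above 0.1, and they were not treated as paired. The culture library names carry numbers of their own, which differed from the replicate numbers at day 3. Pairs by library name were not examined. The spread between replicates exceeded counting error in every group, at 6.15 to 72.0 times per gene.

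The procedure was tested on simulated data built from the same libraries with 100 genes changed 2-fold and 100 changed 4-fold. With the day 3 and tissue layout it recovered 70% and 93%, with 10 false among 173 calls. With the 2 h and 0 h layout it recovered 76% and 95%, with 4 false among 175 calls, and with litter as a block 85% and 98%, with 10 false among 193. Noise and litter effects were drawn independently for each simulated gene, so these rates may not hold where genes vary together. As alternatives, edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads.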

Results

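The libraries profiled messenger RNA from a culture model of the newborn rat testis, in which all cell types of testes from 5-day-old Sprague Dawley rats were grown together in an extracellular matrix gel without serum. There were 24 libraries in 8 groups of 3, from 2 experiments. In the baseline experiment, cells of 1 litter were sequenced as the fresh isolate (called tissue here) and after 3, 5 and 7 days of culture. Its 3 libraries per group were technical replicates, so its p-values measured technical spread and not variation between litters. In the induction experiment, cultures of 3 litters received luteinizing hormone (LH) and follicle-stimulating hormone (FSH) with fresh medium on day 10 and were sequenced at 0, 2, 12 and 48 h, with 1 library per litter and time. No untreated libraries at 2, 12 or 48 h were analysed here, so hormone, fresh medium and time in culture could not be separated, and the 6 h time point was not analysed here.

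Expression was given in CPM, the reads of a gene scaled to a common library total, where 1 read was worth 0.0329 to 0.0579 CPM in the baseline libraries (17.3 to 30.4 M reads) and 0.0353 to 0.0633 CPM in the induction libraries (15.8 to 28.3 M reads). A level of 0 allowed up to 3 reads, or 0.0987 to 0.174 CPM and 0.106 to 0.19 CPM, for counting error only. Levels are means ± SD and log2 fold changes are given ± SE, with n = 3 libraries per group throughout, and all adjusted p-values came from limma. On the first principal component, which held 71.7% of the variance of the baseline libraries, the tissue libraries lay at 76.4 to 78.9 and the 9 culture libraries at -33.2 to -17.8. In the induction libraries the first component held 33.7% and the second 24.4%. Levels were not tested between the experiments. Chosen after values were seen, Eef1a1, an abundant translation factor, had a mean of 7107 CPM in the baseline libraries and 0.362 CPM in the induction libraries. Fth1, the ferritin heavy chain, had 0 and 1336 CPM. They were among 218 genes with a mean over 20 CPM in 1 experiment and under 1 CPM in the other, as were Insl3, Mapk13, Mmp11 and Mmp28. Counting of these genes is uncertain, except that Mapk13 was among them only through its tissue level.

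Fos and Fosb, immediate early transcription factors that cells switch on within minutes of a stimulus, were far lower after 3 days of culture than in tissue. Fosb fell from 1179 ± 40.1 to 3.42 ± 0.791 CPM (log2 fold change -8.07 ± 0.18, limma adjusted p = 6.28e-12) and Fos fell from 1330.4 ± 13.4 to 6.17 ± 1.87 CPM (-7.57 ± 0.21, adjusted p = 3.59e-11). Hspa1b, a heat shock chaperone made when proteins are damaged, fell from 1595 ± 71.8 to 6.70 ± 2.02 CPM (-7.73 ± 0.26, adjusted p = 1.49e-10). Hspa1a, its near-identical copy, fell from 54.6 ± 3.90 to 0.156 ± 0.192 CPM (-5.60 ± 0.17, adjusted p = 5.84e-11), and the division of reads between the copies is uncertain. The nuclear receptor Nr4a1, another immediate early gene, fell from 876 ± 18.9 to 19.5 ± 0.733 CPM (-5.42 ± 0.27, adjusted p = 5.19e-09). Among rising genes, the network collagen Col8a1 went from 0.303 ± 0.137 to 107 ± 9.49 CPM (6.38 ± 0.19, adjusted p = 5.38e-11) and the mesothelial membrane protein Lrrn4 went from 0.448 ± 0.174 to 115 ± 9.70 CPM (6.33 ± 0.27, adjusted p = 1.09e-09). The growth factor Bmp3, the neuropeptide precursor Pnoc and the Sertoli cell protein Testin rose by log2 fold changes of 6.12 ± 0.19, 5.29 ± 0.19 and 5.21 ± 0.14, each with limma adjusted p of at most 2.56e-10. Of 13055 genes tested with limma, 3801 rose and 3498 fell, 1281 and 1052 of them by at least 2-fold. The comparison asked how the cells' messenger RNA differed between fresh isolate and early culture.

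The immediate early, cAMP and CREB, heat shock and glucocorticoid lists were lower at day 3. Among immediate early genes, 18 of 19 fell and 0 rose (18 and 0 adjusted over the list alone). For the immediate early list, limma camera gave adjusted p = 2.22e-15, and adjusted p = 0.0163 with an estimated correlation. Klf4, a transcription factor of this list, fell by -4.94 ± 0.25. Among targets of cAMP and its transcription factor CREB, 12 of 15 fell and 3 rose (12 and 3 adjusted over the list alone). For the cAMP and CREB list, limma camera gave adjusted p = 4.88e-05, and adjusted p = 0.0163 with an estimated correlation. Within that list Nr4a2 and Nr4a3 fell by -3.61 ± 0.19 and -3.59 ± 0.27, while the scaffold protein Akap12 rose by 1.75 ± 0.18. Among heat shock genes 10 of 12 fell and 0 rose (10 and 0 adjusted over the list alone). For the heat shock list, limma camera gave adjusted p = 2.11e-07, and adjusted p = 0.0126 with an estimated correlation. The chaperone regulators Hsph1 and Bag3 had log2 fold changes of -2.65 ± 0.14 and -2.19 ± 0.15 (limma adjusted p of at most 9.97e-08). Of glucocorticoid-responsive genes, 6 of 8 fell and 0 rose (6 and 0 adjusted over the list alone), with Errfi1, Zbtb16, Klf9 and Per1 at -2.41 ± 0.12, -2.41 ± 0.24, -1.71 ± 0.22 and -1.09 ± 0.15. For the glucocorticoid list, limma camera gave adjusted p = 0.00730, and adjusted p = 0.343 with an estimated correlation. As fixed, it shared 1 gene each with the immediate early, cAMP and CREB and germ cell lists, the last being Zbtb16. Its call was thus not independent of theirs. Mitochondrial rRNA and tRNA together stood at 5438 ± 801 CPM in tissue, 400 ± 85.1 CPM at day 3, 365 ± 63.2 CPM at day 5 and 254 ± 14.3 CPM at day 7.

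Germ cell messenger RNAs were also lower at day 3. Ddx4, an RNA helicase of the germ line, fell from 38.9 ± 1.17 to 2.72 ± 1.64 CPM (log2 fold change -3.55 ± 0.31, limma adjusted p = 6.99e-07), and the RNA-binding regulator Dazl fell from 93.8 ± 3.95 to 7.32 ± 3.83 CPM (-3.65 ± 0.38, adjusted p = 3.78e-06). Mael, which silences transposons, and the spermatogonial factor Sohlh1 fell by -3.16 ± 0.25 and -2.96 ± 0.26. Across germ cell markers, 18 of 19 fell and 0 rose (19 and 0 adjusted over the list alone). For the germ cell list, limma camera gave adjusted p = 6.27e-11, and adjusted p = 0.0815 with an estimated correlation. Across meiosis genes, 7 of 7 fell and 0 rose (7 and 0 adjusted over the list alone), including Smc1b, Hormad1, Dmc1 and Sycp1 at -2.92 ± 0.23, -2.57 ± 0.19, -2.46 ± 0.17 and -2.21 ± 0.31. For the meiosis list, limma camera gave adjusted p = 0.000119, and adjusted p = 0.126 with an estimated correlation. Cell cycle genes moved down too, as 24 of 26 fell and 0 rose (25 and 0 adjusted over the list alone). For the cell cycle list, limma camera gave adjusted p = 7.92e-09, and adjusted p = 0.156 with an estimated correlation. Bub1, a spindle checkpoint kinase, fell from 175 ± 10.1 to 67.4 ± 4.73 CPM (-1.37 ± 0.12, adjusted p = 8.32e-07) and Mcm2, part of the replicative helicase, fell from 361 ± 10.1 to 151 ± 12.0 CPM (-1.25 ± 0.09, adjusted p = 1.02e-07). Bub1b and Birc5 had log2 fold changes of -1.10 ± 0.12 and -1.06 ± 0.20. For oxidative phosphorylation, 11 of 17 fell and 0 rose (11 and 0 adjusted over the list alone), with the ATP synthase subunit Atp5f1b from 1699 ± 146 to 1078 ± 87.7 CPM. For the oxidative phosphorylation list, limma camera gave adjusted p = 0.0248, and adjusted p = 0.485 with an estimated correlation.

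Contractile, matrix and mesothelial genes were higher at day 3. Synm, an intermediate filament protein of muscle, rose by a log2 fold change of 2.78 ± 0.12 (limma adjusted p = 1.14e-09), and Actg2, a smooth muscle actin, rose from 26.8 ± 2.54 to 162 ± 15.1 CPM (2.55 ± 0.15, adjusted p = 2.19e-08). Tagln and Smtn rose by 2.09 ± 0.15 and 1.27 ± 0.16. In the list of peritubular myoid and smooth muscle cells, 9 of 10 rose and 0 fell (9 and 0 adjusted over the list alone). For the myoid list, limma camera gave adjusted p = 0.000106, and adjusted p = 0.0287 with an estimated correlation. Among extracellular matrix genes 19 of 22 rose and 0 fell (19 and 0 adjusted over the list alone). For the matrix list, limma camera gave adjusted p = 4.16e-06, and adjusted p = 0.216 with an estimated correlation. Lox, which crosslinks collagen, rose from 25.1 ± 1.15 to 408 ± 37.9 CPM (3.97 ± 0.25, adjusted p = 3.34e-08), and Bgn, Fn1 and Postn rose by 2.71 ± 0.15, 2.59 ± 0.25 and 2.43 ± 0.46. In the mesothelial list 3 of 4 rose and 0 fell (3 and 0 adjusted over the list alone), with Wnt4 at 2.80 ± 0.17 and Upk1b at 2.74 ± 0.20. For the mesothelial list, limma camera gave adjusted p = 0.00599, and adjusted p = 0.180 with an estimated correlation. In the list of p53 targets and cell cycle arrest 6 of 11 rose and 1 fell (6 and 1 adjusted over the list alone). For the p53 list, limma camera gave adjusted p = 0.0274, and adjusted p = 0.343 with an estimated correlation. Its Cdkn2b, an inhibitor of cell cycle kinases, rose from 9.22 ± 0.549 to 99.3 ± 12.8 CPM (3.29 ± 0.28, adjusted p = 6.21e-07), and Mdm2, which degrades p53, fell by -0.52 ± 0.13.

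Genes of the hormone-producing and supporting cells moved in different directions at day 3. Cyp17a1, which makes androgen precursors in Leydig cells, fell from 12.3 ± 1.26 to 0.448 ± 0.239 CPM (log2 fold change -3.20 ± 0.24, limma adjusted p = 1.77e-07), and Hsd17b3, which completes testosterone, fell from 47.6 ± 0.888 to 16.0 ± 2.59 CPM (-1.52 ± 0.15, adjusted p = 1.79e-06). Insl3, a Leydig cell hormone, rose from 5.04 ± 0.324 to 30.9 ± 5.08 CPM (2.39 ± 0.15, adjusted p = 3.45e-08), although it overlaps B3gnt3 in the annotation, unstranded counting cannot separate them, and it had 0 CPM in all induction groups. Amh, made by immature Sertoli cells, rose from 232 ± 20.8 to 551 ± 93.3 CPM (1.24 ± 0.21, adjusted p = 0.000236), and the Sertoli cell regulator Sox9 rose from 102 ± 4.43 to 185 ± 7.13 CPM (0.85 ± 0.12, adjusted p = 5.22e-05). The inhibin subunit Inha fell by -0.47 ± 0.12 and Inhba rose by 2.02 ± 0.12. The FSH receptor Fshr (-0.36 ± 0.18, limma adjusted p = 0.112), Cyp11a1 (-0.34 ± 0.21, 0.189) and the macrophage receptor Csf1r (-0.19 ± 0.27, 0.565) did not pass, but Fshr passed without day 3 replicate 2 (0.0242). The LH receptor Lhcgr fell from 1.18 ± 0.150 to 0.0922 ± 0.0341 CPM (adjusted p = 0.0460), to 3 reads or fewer per library. That call was lost without any 1 of the tissue or day 3 libraries (0.082 to 0.111), day 5 replicate 1 (0.0514) or day 7 replicate 1 (0.0528). Of Leydig cell markers, 5 of 9 fell and 3 rose (5 and 3 adjusted over the list alone), and the list was not called. For the Leydig cell list, limma camera gave adjusted p = 0.337, and adjusted p = 0.631 with an estimated correlation. Of Sertoli cell markers, 6 of 12 rose and 1 fell (6 and 1 adjusted over the list alone). For the Sertoli cell list, limma camera gave adjusted p = 0.347, and adjusted p = 0.631 with an estimated correlation. Among macrophage markers 2 of 10 fell and 1 rose (1 and 1 adjusted over the list alone). For the macrophage list, limma camera gave adjusted p = 0.753, and adjusted p = 0.882 with an estimated correlation. In that list Tyrobp, a signalling adaptor of myeloid cells, fell from 23.8 ± 3.80 to 1.88 ± 0.909 CPM (-3.14 ± 0.25, adjusted p = 2.53e-07).

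**Figure D1:**
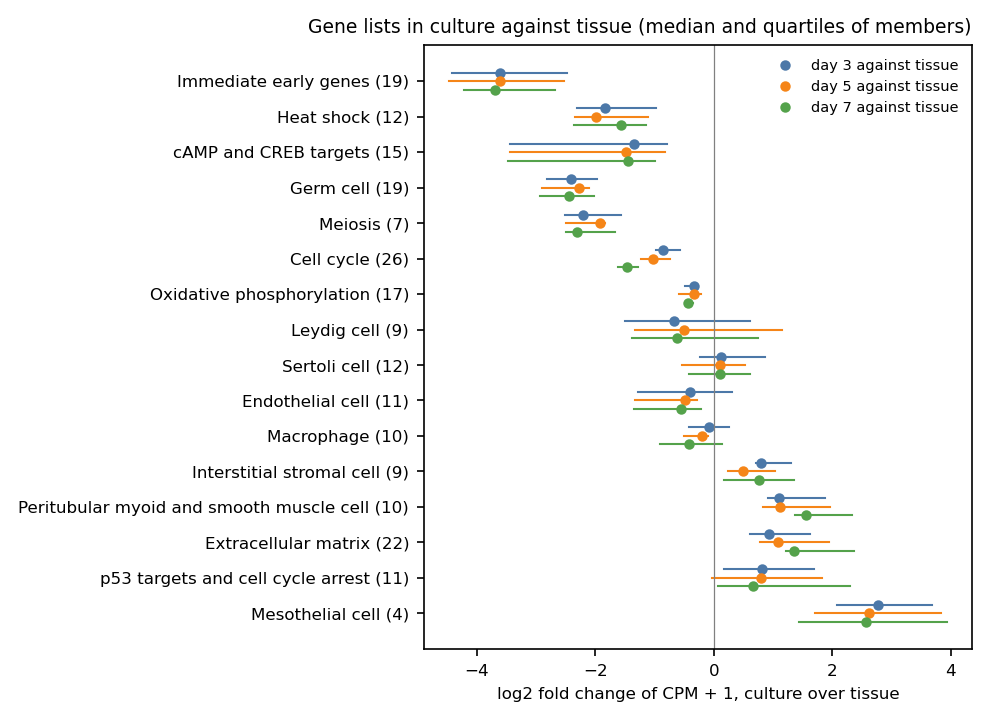
Log2 fold change of the members of 16 gene lists (points, medians; lines, quartiles) at day 3, 5 and 7 against tissue. The immediate early genes had medians of -3.61, -3.62 and -3.70 and the extracellular matrix genes of 0.94, 1.09 and 1.36.

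By day 5 the strongest reductions were again in Fosb and Hspa1b. Fosb, an immediate early gene, fell from 1179 ± 40.1 to 5.21 ± 0.854 CPM (log2 fold change -7.58 ± 0.18, limma adjusted p = 1.46e-11), and the chaperone Hspa1b fell from 1595 ± 71.8 to 9.03 ± 3.47 CPM (-7.37 ± 0.26, adjusted p = 2.12e-10). Fos and Nr4a1 fell by -6.83 ± 0.21 and -5.85 ± 0.27. Mapk13, a stress-activated kinase of epithelia, fell from 128 ± 1.51 to 1.06 ± 0.418 CPM (-5.99 ± 0.22, adjusted p = 3.16e-10). It was among the 218 genes through its tissue level, and its day 5 level lay near its induction mean of 0.781 CPM. The collagen Col8a1 rose from 0.303 ± 0.137 to 106 ± 15.4 CPM (6.36 ± 0.19, adjusted p = 5.76e-11), and Bmp3, Lrrn4, Pnoc and Testin rose by 6.24 ± 0.19, 6.10 ± 0.27, 5.23 ± 0.19 and 5.03 ± 0.14. With limma, 3863 of 13055 genes rose and 3952 fell, 1320 and 1361 of them by at least 2-fold.

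Reduced groups at day 5 included the immediate early, heat shock, cAMP and CREB and germ cell lists. Of immediate early genes, 18 of 19 fell and 0 rose (18 and 0 adjusted over the list alone). The immediate early list had a limma camera adjusted p = 2.50e-13, and adjusted p = 0.0275 with an estimated correlation. Of heat shock genes, 9 of 12 fell and 0 rose (10 and 0 adjusted over the list alone). The heat shock list had a limma camera adjusted p = 3.00e-06, and adjusted p = 0.0241 with an estimated correlation. Of targets of cAMP and CREB, 12 of 15 fell and 3 rose (12 and 3 adjusted over the list alone). The cAMP and CREB list had a limma camera adjusted p = 0.000219, and adjusted p = 0.0275 with an estimated correlation. Hspa8, the constitutive heat shock chaperone, fell from 2587 ± 24.6 to 564 ± 58.0 CPM (-2.20 ± 0.10, adjusted p = 2.07e-09). In the germ cell list 19 of 19 fell and 0 rose (19 and 0 adjusted over the list alone), with Ddx4, Mael, Sohlh1 and Piwil4 at -3.53 ± 0.31, -3.17 ± 0.25, -3.11 ± 0.26 and -3.07 ± 0.21. The germ cell list had a limma camera adjusted p = 7.45e-10, and adjusted p = 0.109 with an estimated correlation. In the meiosis list 7 of 7 fell and 0 rose (7 and 0 adjusted over the list alone). The meiosis list had a limma camera adjusted p = 0.000280, and adjusted p = 0.136 with an estimated correlation. For the cell cycle, 24 of 26 fell and 0 rose (25 and 0 adjusted over the list alone). The cell cycle list had a limma camera adjusted p = 7.45e-10, and adjusted p = 0.136 with an estimated correlation. Its Mcm2 and Bub1b fell by -1.55 ± 0.09 and -1.52 ± 0.12. For glucocorticoid-responsive genes 6 of 8 fell and 0 rose (6 and 0 adjusted over the list alone). The glucocorticoid list had a limma camera adjusted p = 0.00722, and adjusted p = 0.337 with an estimated correlation.

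Raised groups at day 5 were again contractile, matrix and mesothelial. In the myoid and smooth muscle list 9 of 10 rose and 0 fell (9 and 0 adjusted over the list alone), with Synm at 2.99 ± 0.12 and Mylk, which activates myosin, at a log2 fold change of 1.29 ± 0.13. The myoid list had a limma camera adjusted p = 0.000134, and adjusted p = 0.0294 with an estimated correlation. In the matrix list 20 of 22 rose and 0 fell (21 and 0 adjusted over the list alone), with Lox from 25.1 ± 1.15 to 543 ± 226 CPM and the fibronectin gene Fn1 from 183 ± 11.7 to 1464 ± 300.3 CPM. The matrix list had a limma camera adjusted p = 2.60e-07, and adjusted p = 0.166 with an estimated correlation. Of mesothelial markers, 3 of 4 rose and 0 fell (4 and 0 adjusted over the list alone). The mesothelial list had a limma camera adjusted p = 0.00453, and adjusted p = 0.166 with an estimated correlation. Of p53 and cell cycle arrest genes, 6 of 11 rose and 2 fell (6 and 2 adjusted over the list alone). The p53 list had a limma camera adjusted p = 0.0350, and adjusted p = 0.337 with an estimated correlation. Without day 5 replicate 3 the p53 list was not called (limma adjusted p = 0.0595). Star, which moves cholesterol into mitochondria for steroid synthesis, rose from 7.60 ± 0.212 to 18.2 ± 1.14 CPM (log2 fold change 1.15 ± 0.18, limma adjusted p = 0.000123). Insl3 rose and Cyp17a1 fell, by 2.62 ± 0.15 and -3.59 ± 0.24, and Inha fell by -1.08 ± 0.12. Amh, which had risen at day 3, did not pass at day 5 (0.25 ± 0.21, limma adjusted p = 0.314) but passed without day 5 replicate 3 (0.0123). The difference between those changes was not tested. Amh did not pass at day 7 against tissue either, under any of 23 alternatives. It was lower at day 7 than at day 3 in limma, a call lost in 3 of 23 alternatives.

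After 7 days Hspa1b, a chaperone, fell from 1595 ± 71.8 to 8.16 ± 2.74 CPM (log2 fold change -7.49 ± 0.26, limma adjusted p = 1.65e-10). Fos and Fosb, immediate early genes, fell by -7.17 ± 0.21 and -7.15 ± 0.18. The kinase Mapk13 fell from 128 ± 1.51 to 0.728 ± 0.436 CPM (-6.25 ± 0.22, adjusted p = 2.16e-10), and Glb1l3, a galactosidase-like enzyme, fell from 186 ± 8.49 to 2.73 ± 1.38 CPM (-5.71 ± 0.28, adjusted p = 3.00e-09). Pnoc rose from 0.806 ± 0.386 to 120.0 ± 15.4 CPM (6.08 ± 0.19, adjusted p = 7.15e-11), Cpz, a secreted carboxypeptidase, rose from 2.96 ± 0.877 to 133 ± 31.4 CPM (5.08 ± 0.23, adjusted p = 1.36e-09), and Col8a1, Lrrn4 and Bmp3 rose by 6.14 ± 0.19, 6.03 ± 0.27 and 5.92 ± 0.19. In limma, 3725 of 13055 genes rose and 4102 fell, 1404 and 1422 of them by at least 2-fold.

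Lists called lower at day 7 included the cell cycle and the immediate early genes. For the cell cycle, 26 of 26 fell and 0 rose (26 and 0 adjusted over the list alone), with Bub1 from 175 ± 10.1 to 41.3 ± 6.80 CPM and the proliferation antigen Mki67 from 327 ± 30.0 to 130.4 ± 23.2 CPM. For the cell cycle list, limma camera gave adjusted p = 9.15e-13, and adjusted p = 0.106 with an estimated correlation. Among immediate early genes, 18 of 19 fell and 0 rose (18 and 0 adjusted over the list alone). For the immediate early list, limma camera gave adjusted p = 9.15e-13, and adjusted p = 0.0178 with an estimated correlation. Among heat shock genes, 10 of 12 fell and 0 rose (10 and 0 adjusted over the list alone). For the heat shock list, limma camera gave adjusted p = 5.14e-06, and adjusted p = 0.0178 with an estimated correlation. Among targets of cAMP and CREB, 12 of 15 fell and 3 rose (12 and 3 adjusted over the list alone). For the cAMP and CREB list, limma camera gave adjusted p = 0.000140, and adjusted p = 0.0178 with an estimated correlation. Among germ cell markers 19 of 19 fell and 0 rose (19 and 0 adjusted over the list alone), with Ddx4 and Dazl at -3.86 ± 0.31 and -3.26 ± 0.38. For the germ cell list, limma camera gave adjusted p = 2.79e-09, and adjusted p = 0.109 with an estimated correlation. Among meiosis genes 7 of 7 fell and 0 rose (7 and 0 adjusted over the list alone). For the meiosis list, limma camera gave adjusted p = 0.000509, and adjusted p = 0.135 with an estimated correlation. Among genes of oxidative phosphorylation 11 of 17 fell and 0 rose (11 and 0 adjusted over the list alone), with Atp5f1b at -0.80 ± 0.11 and Uqcrc2, a subunit of respiratory complex III, at -0.48 ± 0.12. The oxidative phosphorylation list had a limma camera adjusted p = 0.0172, and adjusted p = 0.510 with an estimated correlation.

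Contractile, matrix, mesothelial and p53 lists were called higher at day 7. Among myoid and smooth muscle genes 9 of 10 rose and 0 fell (9 and 0 adjusted over the list alone), with Synm, Actg2, Tagln and Lmod1 at 3.36 ± 0.12, 2.77 ± 0.15, 2.58 ± 0.15 and 1.58 ± 0.17. For the myoid list, limma camera gave adjusted p = 3.09e-06, and adjusted p = 0.0178 with an estimated correlation. Acta2, a smooth muscle actin, rose from 743 ± 47.5 to 1919.6 ± 191 CPM (log2 fold change 1.37 ± 0.15, limma adjusted p = 5.06e-06). Among matrix genes 21 of 22 rose and 0 fell (21 and 0 adjusted over the list alone), with the crosslinker Lox from 25.1 ± 1.15 to 471 ± 161 CPM, the proteoglycan Bgn from 639 ± 24.7 to 6096 ± 1346 CPM and Tnc, a matrix glycoprotein, from 2.88 ± 0.114 to 31.9 ± 16.6 CPM. For the matrix list, limma camera gave adjusted p = 1.77e-09, and adjusted p = 0.135 with an estimated correlation. For the list of p53 targets and cell cycle arrest, 7 of 11 rose and 1 fell (7 and 1 adjusted over the list alone). For the p53 list, limma camera gave adjusted p = 0.0120, and adjusted p = 0.299 with an estimated correlation. Cdkn1a, which p53 induces to stop the cell cycle, rose from 18.8 ± 0.882 to 82.9 ± 16.7 CPM (2.06 ± 0.24, adjusted p = 7.87e-06). Among mesothelial markers 3 of 4 rose and 0 fell (3 and 0 adjusted over the list alone). For the mesothelial list, limma camera gave adjusted p = 0.0107, and adjusted p = 0.218 with an estimated correlation. Star rose from 7.60 ± 0.212 to 17.3 ± 2.07 CPM (1.08 ± 0.18, adjusted p = 0.000195) and Insl3 rose from 5.04 ± 0.324 to 45.6 ± 6.07 CPM (2.94 ± 0.15, adjusted p = 4.78e-09), while Hsd17b3 fell from 47.6 ± 0.888 to 17.8 ± 1.97 CPM (-1.37 ± 0.15, adjusted p = 3.54e-06). Lhcgr went from 1.18 ± 0.150 to 1.96 ± 2.35 CPM and did not pass (limma adjusted p = 0.767). Csf1r fell from 5.58 ± 1.20 to 2.34 ± 0.573 CPM (-0.97 ± 0.27, adjusted p = 0.00649), but the macrophage list was not called, where 4 of 10 fell and 1 rose (4 and 1 adjusted over the list alone). The macrophage list had a limma camera adjusted p = 0.376, and adjusted p = 0.741 with an estimated correlation.

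**Figure D2:**
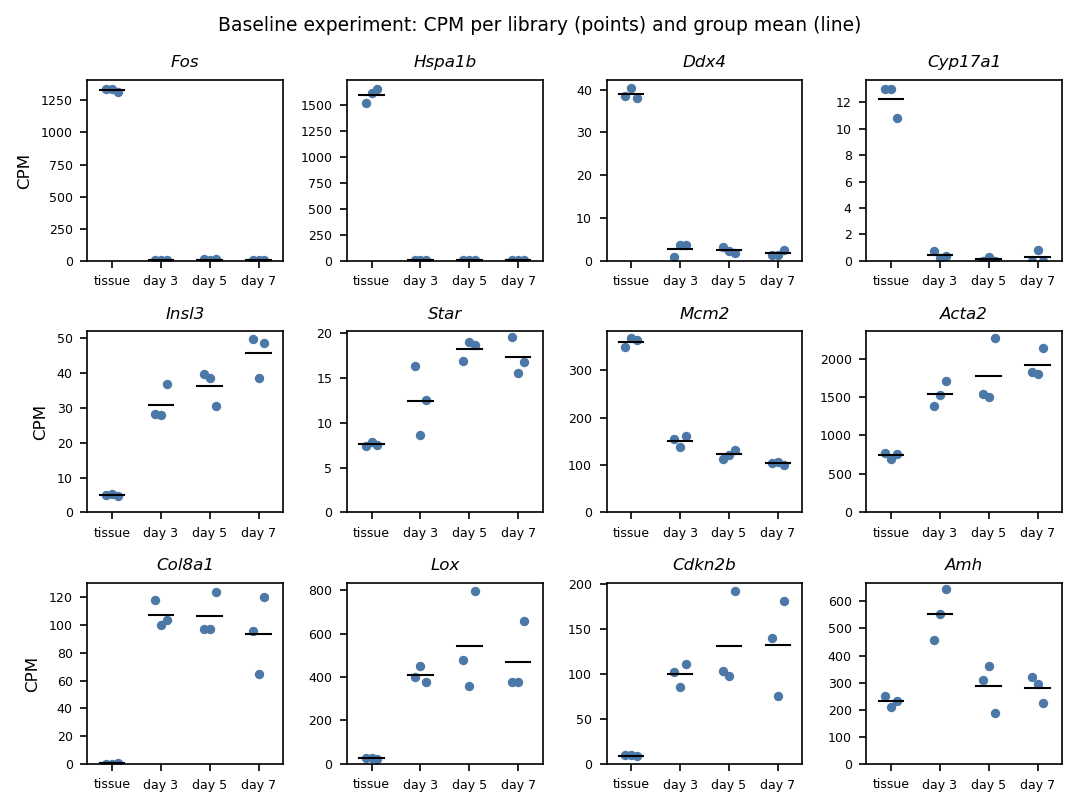
Expression in CPM of 12 genes in each baseline library (points) with the group mean (line), for tissue and culture days 3, 5 and 7. Fos goes from a mean of 1330 CPM in tissue to between 6.17 and 10.8 CPM in culture, and Lox from 25.1 CPM to between 408 and 543 CPM.

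Between day 3 and day 7 the elastin gene Eln, which gives tissue its recoil, rose from 287 ± 144 to 1586 ± 476 CPM (log2 fold change 2.54 ± 0.30, limma adjusted p = 0.000831). Adamtsl2, a microfibril-binding protein, rose from 4.53 ± 3.92 to 49.5 ± 16.2 CPM (3.42 ± 0.55, adjusted p = 0.00470), Itih5, which binds hyaluronan, rose by 2.53 ± 0.24, and the protease inhibitor Serpine2 and the vesicle protein Sytl2 rose by 2.50 ± 0.22 and 3.01 ± 0.58. Rlim, a ubiquitin ligase, fell from 12.4 ± 1.57 to 0.144 ± 0.0631 CPM (-3.55 ± 0.16, adjusted p = 9.17e-08). It was tested in 20 of 23 alternatives and missed the filter without any 1 of the day 3 libraries. No tissue, day 5 or day 7 library therefore reached 1 CPM of Rlim, and whether expression or counting differed at day 3 was not tested. The cadherin Cdh20 fell from 20.9 ± 2.93 to 6.09 ± 0.890 CPM (-1.63 ± 0.18, adjusted p = 0.000428). Alas2, which starts haem synthesis in red cells, fell from 45.5 ± 6.29 to 15.8 ± 9.54 CPM (-1.60 ± 0.37, adjusted p = 0.0290). Without day 3 replicate 1 Sytl2 did not pass (0.0503), nor Alas2 without any 1 of the day 3 libraries (up to 0.0908) or day 7 replicates 1 and 2 (0.113 and 0.0985). In limma 177 genes rose and 318 fell, 66 and 49 of them by at least 2-fold. Of the 495 calls 35.76% were rises, against 50.1% after median-of-ratios scaling. The count was 181, 294, 827, 328 and 210 without the day 3 replicates 1 and 2, day 5 replicate 3 and day 7 replicates 1 and 3 in turn.

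The cell cycle list declined further between these days, as 22 of 26 fell and 0 rose (24 and 0 adjusted over the list alone). The cell cycle list had a limma camera adjusted p = 6.78e-29, and adjusted p = 0.0273 with an estimated correlation. Rrm2, which makes DNA building blocks, fell from 42.1 ± 3.70 to 21.6 ± 2.05 CPM (log2 fold change -0.93 ± 0.11, limma adjusted p = 0.000538), and the mitotic kinase Plk1 and the helicase subunit Mcm5 fell by -0.76 ± 0.10 and -0.76 ± 0.12. In the myoid and smooth muscle list 4 of 10 rose and 0 fell (6 and 0 adjusted over the list alone). The myoid list had a limma camera adjusted p = 1.83e-08, and adjusted p = 0.0131 with an estimated correlation. Myh11, smooth muscle myosin, rose by 0.95 ± 0.14. In the matrix list 4 of 22 rose and 0 fell (9 and 0 adjusted over the list alone). The matrix list had a limma camera adjusted p = 8.63e-16, and adjusted p = 0.0893 with an estimated correlation. Fibrillar collagen Col1a1 rose from 3625 ± 472 to 8344 ± 2192 CPM (1.18 ± 0.18, adjusted p = 0.00405), and Col3a1 and Col5a1 rose by 0.89 ± 0.13 and 0.60 ± 0.09. Mmp2, a gelatinase, rose from 303 ± 29.9 to 621 ± 37.3 CPM (1.04 ± 0.09, adjusted p = 9.97e-05). In the p53 list 2 of 11 rose and 0 fell (2 and 1 adjusted over the list alone), with Ccng1 at 0.65 ± 0.12. The p53 list had a limma camera adjusted p = 0.0113, and adjusted p = 0.621 with an estimated correlation. The call was lost without day 3 replicate 2 or day 7 replicate 1 (limma adjusted p up to 0.115). Ptgds, a prostaglandin synthase of Sertoli cells, fell from 4.33 ± 2.34 to 0.585 ± 0.416 CPM (-1.69 ± 0.28, adjusted p = 0.00538). Germ cell Ddx4 (-0.31 ± 0.31, limma adjusted p = 0.759) and Cyp17a1 (-0.23 ± 0.24, 0.771) did not pass. In the germ cell list the median was -0.05 and the mean was negative, while the test pointed up (limma camera adjusted p = 0.704).

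At 2 h after LH and FSH, Nr4a1, an immediate early receptor induced by gonadotropins in Leydig cells, stood at a mean of 66.2 ± 18.6 CPM against 31.0 ± 14.0 CPM at 0 h (log2 fold change 1.12 ± 0.32). Its change was 1.14, 0.40 and 1.81 in litters 1, 2 and 3. Star, the cholesterol transporter, stood at 118 ± 67.1 CPM against 50.9 ± 13.5 CPM (1.09 ± 0.35), with 0.86, 1.81 and 0.60 in the litters. Neither passed in limma, with adjusted p = 0.232 and 0.274, while DESeq2 called both (0.0257 and 0.0192). In limma 0 of 12450 genes passed and 1327 had an unadjusted p under 0.05, against 6 calls in edgeR and 378 in DESeq2. The comparison asked what changed early after the hormones and fresh medium were given.

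With litter as a block, limma called 77 genes, 41 up and 36 down, edgeR 87 and DESeq2 512. Idi1, an enzyme of the cholesterol pathway, rose from 35.5 ± 4.44 to 70.4 ± 7.92 CPM (log2 fold change 0.97 ± 0.16, limma adjusted p = 0.0414), and Hmgcs1 and Sqle of the same pathway rose by 0.75 ± 0.14 and 0.68 ± 0.12 (adjusted p = 0.0481 and 0.0414). Fdx1, which passes electrons to steroid enzymes, rose from 17.5 ± 0.647 to 32.5 ± 7.78 CPM (0.83 ± 0.14, adjusted p = 0.0414), and Coq10b rose by 0.77 ± 0.12. Speg, a muscle kinase, fell from 26.9 ± 1.75 to 15.1 ± 1.58 CPM (-0.80 ± 0.12, adjusted p = 0.0394), and Hspa12b, Cd80, Slc8b1 and Senp7 fell by -0.57 ± 0.09, -0.61 ± 0.10, -0.63 ± 0.12 and -0.60 ± 0.12. Srxn1, Gclc and Txnrd1, antioxidant genes, rose by 0.83 ± 0.14, 0.60 ± 0.11 and 0.28 ± 0.05, and the clock genes Bmal1 and Cry1 by 0.47 ± 0.08 and 0.44 ± 0.06. The blocked count was 0 without any 1 of the litter 1, 2 and 3 libraries at 0 h, litters 1 and 3 at 2 h, litter 1 at 12 h, or litters 2 and 3 at 48 h. It was 32 without litter 2 at 2 h, 11 and 221 without litters 2 and 3 at 12 h, and 136 without litter 1 at 48 h.

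Lists called at 2 h were all higher. Among genes of cholesterol synthesis and uptake 0 of 21 rose (12 adjusted over the list alone) and 3 with the litter block (14 adjusted over the list alone), and the list was called. For the cholesterol list, limma camera gave adjusted p = 9.25e-11, and adjusted p = 0.447 with an estimated correlation. Among immediate early genes 0 of 19 rose (3 adjusted over the list alone) and 0 with the litter block (5 adjusted over the list alone), and the list was called. The immediate early list had a limma camera adjusted p = 3.63e-06, and adjusted p = 0.447 with an estimated correlation. It was not called without the litter 3 library at 2 h, where adjusted p = 0.109, within a range of 5.18e-11 to 0.109 over its alternatives. Among targets of cAMP and CREB 0 of 14 rose (3 adjusted over the list alone) and 0 with the litter block (6 adjusted over the list alone), with Crem, a cAMP-induced repressor, at 0.35 ± 0.20, and 4 tested genes were shared with the immediate early list. The cAMP and CREB list had a limma camera adjusted p = 4.93e-05, and adjusted p = 0.447 with an estimated correlation. Among oxidative stress genes 0 of 12 rose (3 adjusted over the list alone) and 3 with the litter block (4 adjusted over the list alone). For the oxidative stress list, limma camera gave adjusted p = 4.93e-05, and adjusted p = 0.447 with an estimated correlation. Among circadian clock genes 0 of 15 rose (2 adjusted over the list alone) and 2 with the litter block (2 adjusted over the list alone), and without the litter 3 library at 2 h adjusted p = 0.109, in a range from 0.00132. For the clock list, limma camera gave adjusted p = 0.0129, and adjusted p = 0.447 with an estimated correlation. Without that library 8 lists were called in place of 5. Leydig cell markers were not called (limma camera adjusted p = 0.126).

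By 12 h Cyp17a1, the androgen enzyme of Leydig cells, stood at 14.7 ± 9.94 CPM against 0.898 ± 1.03 CPM at 0 h (log2 fold change 3.01 ± 0.74), with 2.88, 3.14 and 3.00 in litters 1, 2 and 3. It did not pass (limma adjusted p = 0.993, and 0.0851 with litter as a block). Cyp11a1, which cuts the cholesterol side chain, stood at 16.1 ± 10.0 CPM against 7.23 ± 2.14 CPM (0.94 ± 0.42, limma adjusted p = 0.993). In limma 0 of 12450 genes passed and 311 had an unadjusted p under 0.05, against 0 calls in edgeR and 9 in DESeq2. With litter as a block the limma count was 0, with 1000 genes at an unadjusted p under 0.05, edgeR called 0 and DESeq2 21. It was 1 without litter 1 at 2 h or 12 h, 10 without litter 1 at 48 h and 4 without litter 3 at 48 h.

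Leydig cell markers were called higher at 12 h, where 0 of 9 rose (1 adjusted over the list alone) and 0 with the litter block (3 adjusted over the list alone). The Leydig cell list had a limma camera adjusted p = 0.00249, and adjusted p = 0.435 with an estimated correlation. Immediate early genes were called lower, where 0 of 19 fell (0 adjusted over the list alone) and 0 with the litter block (1 adjusted over the list alone), and Fos stood at -0.90 ± 0.38. For the immediate early list, limma camera gave adjusted p = 0.00107, and adjusted p = 0.728 with an estimated correlation. For p53 and cell cycle arrest genes called lower, 0 of 10 fell (0 adjusted over the list alone) and 0 with the litter block (0 adjusted over the list alone). For the p53 list, limma camera gave adjusted p = 0.00262, and adjusted p = 0.652 with an estimated correlation. Steroid hormone genes were called higher, where 0 of 13 rose (1 adjusted over the list alone) and 0 with the litter block (2 adjusted over the list alone). For the steroid list, limma camera gave adjusted p = 0.0105, and adjusted p = 0.728 with an estimated correlation. It was not called without the litter 2 library at 0 h or 12 h (adjusted p = 0.0614 and 0.14, in a range of 0.00310 to 0.253). The Leydig cell and steroid lists shared 6 tested genes, so these calls were not independent. Germ cell markers were called lower, where 0 of 19 fell (0 adjusted over the list alone) and 0 with the litter block (0 adjusted over the list alone). The germ cell list had a limma camera adjusted p = 0.00249, and adjusted p = 0.728 with an estimated correlation. It was not called without litter 3 at 0 h or litter 2 at 12 h (0.342 and 0.468, in a range from 2.42e-07). Macrophage markers were called higher, where 0 of 13 rose (0 adjusted over the list alone) and 0 with the litter block (0 adjusted over the list alone). For the macrophage list, limma camera gave adjusted p = 0.00249, and adjusted p = 0.738 with an estimated correlation. It was not called without litter 2 at 0 h or litter 3 at 12 h (0.558 and 0.33, in a range from 4.16e-06). Their median change was -0.09, 0.30 and 1.57 in litters 1, 2 and 3.

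At 48 h Sectm1a, a secreted immune protein, rose from 3.99 ± 4.16 to 57.9 ± 38.5 CPM (log2 fold change 3.68 ± 0.63, limma adjusted p = 0.0324), by 4.87, 2.40 and 3.77 in litters 1, 2 and 3. Lpar1, a receptor for lysophosphatidic acid, rose from 2.61 ± 0.810 to 11.9 ± 3.05 CPM (1.84 ± 0.21, adjusted p = 0.00389). L3mbtl4, a chromatin reader, rose from 1.46 ± 0.578 to 10.1 ± 5.33 CPM (2.09 ± 0.33, adjusted p = 0.0259), and Htr3a, a serotonin receptor, and Frmd7 rose by 1.93 ± 0.32 and 2.10 ± 0.38. Cd93, a receptor of endothelial cells, fell from 77.3 ± 6.58 to 43.6 ± 4.60 CPM (-0.81 ± 0.15, adjusted p = 0.0474), and Tubb6, Rtl5, Rnaseh2b and Adam23 fell by -0.64 ± 0.11, -0.62 ± 0.10, -0.48 ± 0.09 and -0.47 ± 0.09. The matrix protease Mmp11, one of the 218 genes of uncertain counting, rose from 102 ± 7.73 to 162 ± 7.63 CPM (0.66 ± 0.11, adjusted p = 0.0320) and the metal-binding Mt1 rose from 14.0 ± 0.803 to 26.3 ± 3.21 CPM (0.86 ± 0.13, adjusted p = 0.0259). Of 24 alternatives, 20, 18, 16, 14 and 11 lost the calls of Adam23, Cd93, Tubb6, Rnaseh2b and Rtl5. The calls of Sectm1a, Mmp11, L3mbtl4, Mt1 and Lpar1 were lost in 12, 11, 7, 7 and 2 of 24. Those of Frmd7 and Htr3a were lost in 15 and 12 of 23. In limma 43 of 12450 genes rose and 6 fell, 30 and 0 of them by at least 2-fold, against 38 calls in edgeR and 419 in DESeq2. The count of 49 was 7, 23 and 13 without the litter 1, 2 and 3 library at 0 h, 27 and 21 without litters 1 and 3 at 2 h, 25 and 22 without litters 1 and 2 at 12 h, and 9 without litter 1 at 48 h.

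With litter as a block limma called 541 genes at 48 h, 276 up and 265 down, 68 and 10 of them by at least 2-fold, edgeR 523 and DESeq2 937. Cyp17a1 rose from 0.898 ± 1.03 to 25.4 ± 14.6 CPM (log2 fold change 3.71 ± 0.40, limma adjusted p = 0.00210), by 4.58, 3.60 and 2.94 in litters 1, 2 and 3, and did not pass without the block (adjusted p = 0.0646). Without the block it passed in DESeq2 (0.00161), without litter 2 at 2 h (0.0262) and without all of litter 2 (0.0321). Cyp11a1 rose from 7.23 ± 2.14 to 23.7 ± 11.1 CPM (adjusted p = 0.0302) and Scarb1, a receptor for lipoprotein cholesterol, rose from 46.2 ± 1.29 to 77.4 ± 27.7 CPM (0.66 ± 0.17, adjusted p = 0.0487). The inhibin subunits Inha and Inhbb and the activin antagonist Fst rose by 0.56 ± 0.12, 0.48 ± 0.12 and 0.58 ± 0.14. Over 23 alternatives the blocked calls of Scarb1, Fst, Inhbb, Inha and Cyp11a1 were lost in 14, 14, 13, 9 and 8, and that of Cyp17a1 in 0. Prkcb, a protein kinase C, rose from 27.6 ± 17.2 to 109 ± 34.5 CPM (2.06 ± 0.34, adjusted p = 0.0118). Tnc, the matrix glycoprotein, fell from 89.3 ± 75.6 to 28.3 ± 26.9 CPM (-1.66 ± 0.24, adjusted p = 0.00626), Lrrtm3 fell by -1.15 ± 0.16, Clec3b by -1.29 ± 0.23, Col27a1 by -0.92 ± 0.18 and Adamtsl3 by -0.90 ± 0.19. The mitochondrial Mt-nd2 fell from 574 ± 176 to 289.5 ± 90.8 CPM (-0.99 ± 0.22, adjusted p = 0.0341), a call lost without litters 2 and 3 at 0 h or litters 1 and 3 at 48 h (0.116 to 0.163). The share of reads in mitochondrial protein genes went from 0.553 to 0.473%, 1.05 to 0.550% and 0.643 to 0.302% between 0 and 48 h in litters 1, 2 and 3. Of the 541 calls 51.02% were rises, against 65.88% after median-of-ratios scaling. The count was 358, 130 and 136 without litters 1, 2 and 3 at 0 h, 350 and 349 without litter 1 at 2 h and 12 h, and 153 and 251 without litters 1 and 3 at 48 h.

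Leydig cell markers were called higher at 48 h, where 0 of 9 rose (2 adjusted over the list alone) and 3 with the litter block (3 adjusted over the list alone). For the Leydig cell list, limma camera gave adjusted p = 0.000474, and adjusted p = 0.248 with an estimated correlation. Steroid hormone genes were called higher, where 0 of 13 rose (2 adjusted over the list alone) and 3 with the litter block (3 adjusted over the list alone). The steroid list had a limma camera adjusted p = 0.00207, and adjusted p = 0.696 with an estimated correlation. It was not called without litter 2 at 48 h, where adjusted p = 0.0755 in a range from 0.000218. These lists shared 6 tested genes, of 9 and 13. Glucocorticoid-responsive genes were called higher, where 0 of 8 rose (4 adjusted over the list alone) and 1 with the litter block (5 adjusted over the list alone), and the chaperone Fkbp5 rose from 97.7 ± 7.56 to 138 ± 10.7 CPM (log2 fold change 0.49 ± 0.08, limma adjusted p = 0.00798) with the block. For the glucocorticoid list, limma camera gave adjusted p = 0.000171, and adjusted p = 0.248 with an estimated correlation. Cholesterol genes were called lower, where 0 of 21 fell (0 adjusted over the list alone) and 2 with the litter block (10 adjusted over the list alone), and Nsdhl and Fdft1 fell by -0.57 ± 0.13 and -0.41 ± 0.10. The cholesterol list had a limma camera adjusted p = 9.80e-05, and adjusted p = 0.723 with an estimated correlation. Immediate early genes were called lower, where 0 of 19 fell (0 adjusted over the list alone) and 2 with the litter block (2 adjusted over the list alone), including Egr1 at -0.52 ± 0.09. The immediate early list had a limma camera adjusted p = 0.000745, and adjusted p = 0.723 with an estimated correlation. Macrophage markers were called higher, where 0 of 13 rose (0 adjusted over the list alone) and 2 with the litter block (12 adjusted over the list alone). The macrophage list had a limma camera adjusted p = 0.000147, and adjusted p = 0.723 with an estimated correlation. It was not called without litter 3 at 48 h, where adjusted p = 0.0655 in a range from 9.50e-15. Lyz2, the lysozyme of macrophages, rose from 69.7 ± 66.2 to 171 ± 120.5 CPM (1.35 ± 0.30, adjusted p = 0.0347) with the block. Over 23 alternatives the blocked calls of Fdft1, Nsdhl, Lyz2, Egr1 and Fkbp5 were lost in 16, 12, 9, 4 and 1.

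**Figure D3:**
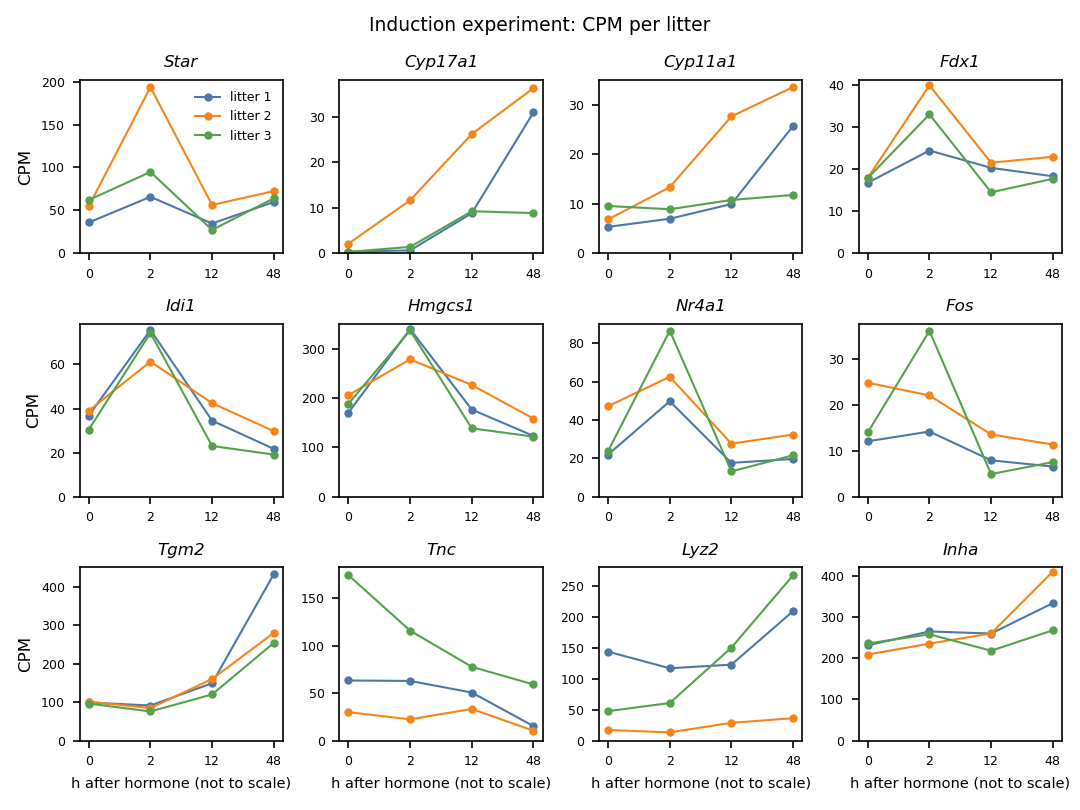
Expression in CPM of 12 genes at 0, 2, 12 and 48 h (positions not to scale in time), with 1 line per litter. Cyp17a1 has means of 0.898, 4.54, 14.7 and 25.4 CPM, and Star of 50.9, 118, 39.3 and 65.4 CPM.

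From 2 h to 12 h Nr4a1 went from 66.2 ± 18.6 to 19.5 ± 7.39 CPM (-1.74 ± 0.32, limma adjusted p = 0.0964). It fell in limma with litter as a block (adjusted p = 0.0204) and in DESeq2 (4.97e-05), and the blocked call was lost without litter 1 at 2 h or litters 2 and 3 at 12 h (0.0752, 0.0606 and 0.064). Star, for cholesterol transport, fell from 118 ± 67.1 to 39.3 ± 15.1 CPM (log2 fold change -1.48 ± 0.24, limma adjusted p = 0.0256) with the block, and Idi1, of cholesterol synthesis, fell from 70.4 ± 7.92 to 33.4 ± 9.77 CPM (-1.09 ± 0.16, adjusted p = 0.0252). In limma without the block 0 of 12450 genes passed and 1654 had an unadjusted p under 0.05, against 11 calls in edgeR and 397 in DESeq2, and 9 genes passed without litter 3 at 2 h. With the block limma called 368 genes, 146 up and 222 down, 4 and 9 of them by at least 2-fold, edgeR 266 and DESeq2 721. Of the 368 calls 39.67% were rises, against 65.22% after median-of-ratios scaling. Cyp17a1 rose from 4.54 ± 6.16 to 14.7 ± 9.94 CPM (1.94 ± 0.40, adjusted p = 0.0386), Kiaa1755 and Crispld2, a secreted lipid-binding protein, rose by 1.05 ± 0.14 and 0.97 ± 0.16, Fam13c rose by 0.86 ± 0.19, the muscle protein Klhl40 fell by -2.11 ± 0.42, and the immediate early genes Fosb, Nr4a3 and Fos fell by -2.46 ± 0.53, -1.63 ± 0.38 and -1.36 ± 0.29. Fam13c and Klhl40 each lost the call without litter 1 or 3 at 2 h or litter 2 or 3 at 12 h (up to 0.153), and under other alternatives. Over 23 alternatives the blocked calls of Nr4a3, Fos, Fosb, Fam13c, Cyp17a1 and Klhl40 were lost in 17, 16, 14, 14, 13 and 11. Those of Star, Crispld2, Idi1, Nr4a1 and Kiaa1755 were lost in 7, 6, 5, 5 and 5. The blocked count was 194 and 140 without litters 1 and 2 at 0 h, 0, 162 and 99 without litters 1, 2 and 3 at 2 h, 57, 0 and 5 without them at 12 h, and 197 and 109 without litters 2 and 3 at 48 h.

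Lists called lower at 12 h than at 2 h included the cholesterol, immediate early, cAMP and CREB, oxidative stress and circadian clock lists. Among cholesterol genes 0 of 21 fell (14 adjusted over the list alone) and 11 with the litter block (17 adjusted over the list alone), with the regulator Insig1 and the enzymes Msmo1 and Hmgcs1 at -0.97 ± 0.18, -0.84 ± 0.16 and -0.84 ± 0.14 with the block. For the cholesterol list, limma camera gave adjusted p = 2.85e-10, and adjusted p = 0.338 with an estimated correlation. Among immediate early genes 0 of 19 fell (13 adjusted over the list alone) and 5 with the litter block (15 adjusted over the list alone). For the immediate early list, limma camera gave adjusted p = 2.79e-11, and adjusted p = 0.338 with an estimated correlation. Among targets of cAMP and CREB 0 of 14 fell (5 adjusted over the list alone) and 3 with the litter block (6 adjusted over the list alone). For the cAMP and CREB list, limma camera gave adjusted p = 1.66e-05, and adjusted p = 0.338 with an estimated correlation. Among oxidative stress genes 0 of 12 fell (3 adjusted over the list alone) and 5 with the litter block (6 adjusted over the list alone), with Srxn1, Gclc, Hmox1 and Gclm at -0.84 ± 0.14, -0.67 ± 0.11, -0.54 ± 0.11 and -0.32 ± 0.07. The oxidative stress list had a limma camera adjusted p = 0.00160, and adjusted p = 0.338 with an estimated correlation. Among circadian clock genes 0 of 15 fell (4 adjusted over the list alone) and 1 with the litter block (4 adjusted over the list alone). The clock list had a limma camera adjusted p = 0.0230, and adjusted p = 0.338 with an estimated correlation. The clock call was lost without litter 3 at 2 h or litters 1 and 2 at 12 h (0.149, 0.0627 and 0.126, in a range from 0.000552). With the block, pericyte markers (limma camera adjusted p = 0.0334, 0.414 with an estimated correlation) and matrix genes (0.00446, 0.489) were also called higher, against 0.0683 and 0.0516 without it.

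Between 12 h and 48 h Tgm2, a crosslinking enzyme, rose from 143 ± 20.8 to 322 ± 96.5 CPM (log2 fold change 1.13 ± 0.12, limma adjusted p = 0.00775) with litter as a block, and Nnat, a small membrane protein, fell from 459.7 ± 133 to 234 ± 40.8 CPM (-0.95 ± 0.08, adjusted p = 0.00291). Prss35, a secreted protease-like protein, fell from 543 ± 100.5 to 351 ± 48.2 CPM (-0.62 ± 0.06, adjusted p = 0.00607), the basement membrane collagen Col4a3 rose from 99.7 ± 14.7 to 215 ± 73.5 CPM (1.06 ± 0.18, adjusted p = 0.0336) and Eppin, a protease inhibitor of the male tract, rose by 1.05 ± 0.16. Pla1a and Lpar1 rose by 1.26 ± 0.22 and 0.96 ± 0.18, Mmp28 (of the same 218 genes), Cmklr1 and Tead4 fell by -0.68 ± 0.10, -0.64 ± 0.10 and -0.69 ± 0.13, and Cdkn1a, a p53 target, rose from 103 ± 18.1 to 170.3 ± 24.0 CPM (0.72 ± 0.12, adjusted p = 0.0336). In limma without the block 0 of 12450 genes passed and 846 had an unadjusted p under 0.05, against 0 calls in edgeR and 85 in DESeq2. With it limma called 89 genes, 54 up and 35 down, 11 and 2 of them by at least 2-fold, edgeR 58 and DESeq2 283. The blocked count was 50 and 46 without litters 1 and 2 at 0 h, 51 without litter 1 at 2 h, 0 and 7 without litters 1 and 2 at 12 h, and 9, 56 and 32 without litters 1, 2 and 3 at 48 h.

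Unfolded protein response genes were called higher between 12 h and 48 h, where 0 of 14 rose (1 adjusted over the list alone) and 0 with the litter block (2 adjusted over the list alone). For the unfolded protein list, limma camera gave adjusted p = 1.42e-05, and adjusted p = 0.441 with an estimated correlation. The p53 and cell cycle arrest genes were called higher, where 0 of 10 rose (3 adjusted over the list alone) and 1 with the litter block (6 adjusted over the list alone). The p53 list had a limma camera adjusted p = 0.000149, and adjusted p = 0.441 with an estimated correlation. Glucocorticoid-responsive genes were called higher, where 0 of 8 rose (0 adjusted over the list alone) and 0 with the litter block (4 adjusted over the list alone). The glucocorticoid list had a limma camera adjusted p = 0.00110, and adjusted p = 0.441 with an estimated correlation. Cholesterol genes were called lower, where 0 of 21 fell (0 adjusted over the list alone) and 0 with the litter block (0 adjusted over the list alone). The cholesterol list had a limma camera adjusted p = 4.14e-06, and adjusted p = 0.664 with an estimated correlation. Star (0.78 ± 0.35, limma adjusted p = 0.728), Cyp17a1 (0.70 ± 0.74, 0.980) and Inha (0.44 ± 0.13, 0.454) did not pass.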

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

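Tests added after the results were seen were the alternatives to the counts with litter as a block, those without litter 2, and the block combined with an estimated correlation; the others were planned. The cause was not tested unless stated. For the genes named without the block, 10648 results under alternatives kept direction and side of the threshold, 322 lost the call and 31 gained one. The kept results included panel genes that had not passed, such as 408 results at 12 h against 0 h, where no gene was called. At 48 h against 0 h 540 results were kept, 145 lost the call and 9 gained one. With the block 1246 kept it and 843 lost it. For lists 1821 kept it, 130 lost it and 4 turned direction. The turned lists were list Extracellular matrix, 12 h against 0 h, without litter 2 at 0 h (adjusted p = 0.979, range 0.000126 to 0.979), list Cell cycle, 12 h against 0 h, without litter 3 at 0 h (0.923, from 1.21e-06), list Interstitial stromal cell, 12 h against 0 h, without litter 3 at 12 h (0.882, from 0.00295) and list Macrophage, 48 h against 12 h, without litter 3 at 48 h (0.877, from 1.33e-11), all from limma camera.

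With an estimated correlation, lists called fell to 4, 4 and 4 for day 3, 5 and 7 against tissue, 2 for day 7 against day 3, and 0 for each of the 5 induction comparisons, also with the litter block. Those that held were the immediate early, heat shock, cAMP and myoid lists against tissue, and the cell cycle and myoid lists for day 7 against day 3. The immediate early and cAMP lists shared 4 members, so their calls were not independent. With the replicate block as well, 3, 0, 4 and 1 lists were called in these baseline comparisons in turn. The baseline replicate numbers did not pair; with them as a block 7229, 7732, 7761 and 485 genes were called. For day 7 against day 3, a fit of these groups alone called 317 genes and DESeq2 802.

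For 2 h against 0 h, where limma called 0, median-of-ratios scaling gave 6, edgeR 6, DESeq2 378 and the litter block 77. At 12 h against 0 h scaling gave 6 lists and DESeq2 9 genes. At 48 h against 0 h the count was 14 with no low-value filter, 2 with these groups alone, 541 with the block, 15 without litter 2 and 419 in DESeq2. For 12 h against 2 h, scaling gave 14 genes and 6 lists, the block 368, edgeR 11 and DESeq2 397. For 48 h against 12 h the block gave 89 and DESeq2 85.

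Counts with the litter block moved more. At 2 h against 0 h they were 8 with no filter, 124 at 5 CPM or more, 45 with median-of-ratios scaling, 294 with the groups alone, 0 without the trend, 0 without litter 2 and 512 in DESeq2. At 12 h against 0 h they were 2 with a pseudocount of 0.1, 1 with the groups alone and 21 in DESeq2. At 48 h against 0 h they were 268 with no filter, 267 with the groups alone, 267 without the trend, 68 without litter 2 and 937 in DESeq2. For 12 h against 2 h they were 96, 5, 0 and 8 in that order, and 721 in DESeq2. For 48 h against 12 h they were 18, 6, 13 and 4 in that order, 58 in edgeR and 283 in DESeq2.

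Leaving out 1 library gave 5946 to 7931 genes and 13 to 15 lists for day 3 against tissue, 6459 to 7970 and 12 to 14 for day 5, 6573 to 8449 and 12 to 12 for day 7, and 181 to 827 and 3 to 7 for day 7 against day 3. It gave 0 to 0 genes and 5 to 8 lists at 2 h, 0 to 0 and 8 to 11 at 12 h, 7 to 49 and 8 to 12 at 48 h against 0 h, 0 to 9 and 8 to 13 for 12 h against 2 h, and 0 to 0 and 6 to 10 for 48 h against 12 h. Blocked counts ranged over 0 to 221 at 2 h, 0 to 10 at 12 h and 130 to 725 at 48 h against 0 h, 0 to 550 for 12 h against 2 h and 0 to 74 for 48 h against 12 h. Depth limited levels under 0.0987 to 0.19 CPM (3 reads).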

Other observations

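All tests of explanations below, including the splits of the libraries, were chosen after the results were seen. At day 7 against tissue, Esrp1, a splicing regulator of epithelia, fell from 33.8 ± 1.16 to 1.49 ± 1.18 CPM (log2 fold change -3.91 ± 0.28, limma adjusted p = 8.19e-08), and Epcam, an epithelial adhesion protein, fell from 32.6 ± 3.64 to 2.52 ± 1.07 CPM (-3.29 ± 0.31, adjusted p = 9.57e-07). The vascular receptor Tie1 fell from 4.52 ± 0.506 to 0.109 ± 0.0946 CPM (-2.32 ± 0.25, adjusted p = 3.46e-06) while Kdr, a receptor for vascular growth factor, rose from 8.95 ± 1.31 to 50.7 ± 8.23 CPM (2.37 ± 0.18, adjusted p = 1.60e-07). The retinoic acid carrier Crabp2 fell from 61.7 ± 6.75 to 1.06 ± 0.296 CPM (-4.93 ± 0.23, adjusted p = 2.41e-09), and the metallothioneins Mt1 and Mt2A fell by -3.89 ± 0.22 and -4.26 ± 0.16. Trib3, a gene of the amino acid stress response, rose from 1.66 ± 0.199 to 13.7 ± 4.04 CPM (2.43 ± 0.27, adjusted p = 4.16e-06), and the glial receptor Erbb3 rose by 2.17 ± 0.20.

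In the induction experiment at 48 h, with litter as a block, Dhrs3, which reduces retinal, rose from 4.90 ± 0.954 to 11.4 ± 3.14 CPM (log2 fold change 1.05 ± 0.18, limma adjusted p = 0.0118). Mt1 and Mt2A rose by 0.86 ± 0.13 and 0.94 ± 0.16, the collagen Col6a1 by 0.58 ± 0.10, the junction protein Jam2 by 0.30 ± 0.05 and the macrophage growth factor Csf1 by 0.28 ± 0.05. Each of these calls was lost when litter 2 was left out.

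The tissue libraries held more immediate early, heat shock and mitochondrial rRNA signal than the cultures. Weaker selection of RNA with a poly-A tail, which would move messenger RNAs alike, was argued against for them. At day 7 against tissue, the immediate early list had an upper quartile of -2.685 and the heat shock list of -1.15 (log2), below the lower quartile of -0.525 of all tested genes. For the mitochondrial rRNA it cannot be told apart, because other RNAs chosen as lacking a tail were also higher in tissue, but by less. The 219 rows of small nuclear, nucleolar and other short non-coding RNAs together were 1.96 times as high in tissue (76.2 ± 9.86 against 38.9 ± 7.67 CPM). The rRNA was 17 times as high (5403 ± 798 against 317 ± 82.1 CPM). An acute response to dissection and dissociation cannot be told apart from the fresh state, as all fresh cells were handled. The heat shock median of -1.557 (log2, day 7 against tissue) is part of the pattern and no separate evidence.

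Between the experiments, 148 genes had more than 20 CPM in the baseline and under 1 CPM in the induction libraries, and 70 the other way. Of the 195 such genes with a position, 43.1% overlapped another gene, against 45 ± 3.55% in 10000 random lists of like level (permutation p = 0.7). Whole gene spans of a reference annotation were compared without strand, and the annotation used for counting was not given. The share therefore cannot decide whether counting treated overlapping genes differently. Reads shared with a named copy or pseudogene may contribute, since 31.3% had one, against 18.1 ± 2.66% (permutation p = 1e-04, the smallest that 10000 lists can give). At day 7 over tissue the 148 genes had a median log2 ratio of -0.203 (quartiles -0.646 to 0.306), where their absence needs -5.44 (-6.62 to -4.9). As a set they were thus still counted at day 7, although Mapk13 was not an example. This cannot test loss of expression by day 7, because they were chosen by a high mean over libraries that are mostly cultures. Genes lost by then would mostly have missed that choice. Of the 70 genes absent from the baseline, 67 were under 1 CPM in tissue, which their choice by a baseline mean under 1 CPM nearly fixed. A loss between day 7 and the induction libraries would have to include the glycolytic enzyme Aldoa, chosen after values were seen, at 805 ± 39.1 CPM on day 7 and 0.312 ± 0.023 CPM at 0 h.

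Macrophage markers at 48 h differed by litter, with median changes of 0.747, 0.00641 and 2.35 in litters 1, 2 and 3. Each change compares 1 library at 48 h with 1 at 0 h, so differences between litters cannot be separated from those between single libraries. Dilution by a lower share of the main cell type, which would raise all other markers alike, was argued against. In litter 3 the highest median of another list was 0.266, against a lower quartile of 1.87 in macrophage markers. In litter 1 the Leydig cell median was 0.722, near that of macrophages, but 9 of 10 other lists had an upper quartile below the macrophage lower quartile of 0.651. A library of another litter under the litter 3 label was also argued against, as its mean correlation was 0.47 with its own litter and 0.198 at most with another. For the litter 1 library this cannot be told apart, with 0.0769 and 0.0303. In both litters 1 and 3, 13 of 13 tested markers were higher, which restates the pattern, so more macrophages cannot be told apart from more transcription per cell.

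With 3 libraries against 3 there are 10 splits, or 4 with litter pairs kept, too few for a share under 0.05. Genes changed in the real split and the highest other split were 7299 and 0 for day 3, 7815 and 0 for day 5, 7827 and 0 for day 7 against tissue, and 495 and 3 for day 7 against day 3, each with 1 split as large. They were 0 and 0 at 2 h (10 splits as large), 0 and 0 at 12 h (10), 49 and 0 at 48 h against 0 h (1), 0 and 0 for 12 h against 2 h (10) and 0 and 3 for 48 h against 12 h (10), by limma. With the block they were 77 and 0 (1 of 4 splits), 0 and 0 (4), 541 and 0 (1), 368 and 0 (1) and 89 and 0 (1). The zero counts had 1327, 311, 1654 and 846 genes at an unadjusted p under 0.05 in that order (1000 at 12 h with the block), with 6, 0, 11 and 0 calls in edgeR and 378, 9, 397 and 85 in DESeq2.

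Lists called in the real split and the highest other split were 15 and 12 for day 3, 14 and 10 for day 5, 12 and 14 for day 7 against tissue, and 6 and 9 for day 7 against day 3, with 1, 1, 2 and 4 splits as large. They were 5 and 11 at 2 h, 10 and 12 at 12 h, 10 and 12 at 48 h against 0 h, 12 and 10 for 12 h against 2 h and 7 and 15 for 48 h against 12 h, with 9, 3, 2, 1 and 5 splits as large. Why other splits called more lists than the real one was not tested. With an estimated correlation the real split called 0 lists in each induction comparison.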
